A study of Drosophila melanogaster with 12 samples.

How the data were processed

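RNA from dissected testes and ovaries of Tdrd5l mutant and cas9 iso control flies raised at 25 °C was sequenced in 12 libraries, 3 per genotype and tissue. Per the labels, 200 ng of RNA went into each library with the TruSeq RNA Library Prep kit v2, a kit that does not mark strand. Testis RNA was depleted of ribosomal RNA and ovary RNA was poly(A) selected, per the labels. The values used here are raw HTSeq gene counts as deposited by the authors, 1 file per library. Per the submitters' processing notes, reads were checked with FastQC, aligned to the BDGP6 genome with TopHat2 2.1.1, counted with HTSeq 0.9.1 and compared with DESeq. The strand setting of the counting, the read length and the description of the lesion are not given in the sources used here.

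Each file lists 17558 features and the summary lines of HTSeq, which were kept out of library sizes and tests. The summary lines held 95.82% to 97.35% of all records in testis libraries and 96.93% to 98.18% in ovary libraries. Records without a feature made up 94.9% to 96.6% of uniquely aligned records in testis and 96.6% to 98.0% in ovary libraries. Records aligned to several places made up 14.77%, 16.63% and 15.79% of all records in mutant testis libraries 1, 2 and 3 and 20.4%, 18.82% and 19.71% in the control testis libraries, without overlap of the genotypes, and 5.65% to 8.8% in ovary libraries. The 10 most counted genes held 10.11% to 15.46% of gene counts in testis and 17.13% to 27.92% in ovary libraries. Gene totals ran from 1390699 to 2880119 counts in testis and from 772292 to 1647933 in ovary libraries.

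Gene symbols, positions and biotypes came from the Ensembl 115 annotation of BDGP6.54, which held 17252 of the features. Of these, 4463 have exon bases opposite an exon of another gene and 12789 have none, and 306 features were not annotated. Antisense RNAs with at least 50% of their exon bases opposite another gene were paired with it and compared as counts per kilobase where a pair had at least 10 counts.

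Before the data were examined, the groups, the comparisons, the tests, the alternatives, the gene lists and the rule for naming genes were fixed. Mutant and control libraries were compared within each tissue with edgeR 4.0.16 (filterByExpr with a minimum count of 10, TMM scaling, robust quasi-likelihood F test, two-sided, Benjamini-Hochberg adjusted p under 0.05). All 12 libraries entered a model with tissue, genotype and their interaction. Calls of the tissues were compared with two-sided Fisher's exact tests over genes tested in both. Per-gene values are TMM-scaled CPM (counts per 1000000) as mean ± SD, and Tdrd5l is given relative to library totals as well. Exact two-sided permutation tests of 3 against 3 libraries have a smallest p of 0.1. Ratios of groups with 1 to 3 counts carry 95% counting intervals, and a group with 0 counts was set against a floor of 3 counts.

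Gene lists numbered 32 with 758 symbols, 736 of them matched in the annotation. They covered germ cell stages (testis stem cell and spermatogonial, tTAF and tMAC, meiotic division, spermatid differentiation, cup and comet, and nurse cell and oocyte meiosis genes), Y-linked fertility and Stellate genes, maternal regulators and axis patterning genes, and chorion, vitelline membrane and yolk protein genes. They also covered piRNA pathway, Tudor domain, P-body, sex determination, ribosomal protein, histone, mitochondrially encoded, DNA damage, heat shock, oxidative stress and immune genes. Markers of somatic cyst and hub, follicle stem and stalk, muscle, fat body, gut, neuronal, accessory gland and hemocyte cells completed them. Lists with at least 3 tested members, 27 in testes and 19 in ovaries, were tested with camera of limma 3.58.1 (preset correlation 0.01, prior count 2), with camera at an estimated correlation and with fry, each adjusted over the lists of a tissue.

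Named genes are Tdrd5l; in each tissue the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose higher mean is at least 5 CPM; up to 4 called members of each list, or up to 2 members with the smallest p if none was called; osk, grk, orb, nanos, bru1, bcd, me31B and tral in both tissues; the 6 genes with the smallest adjusted p for the interaction with at least 5 CPM in a group; and up to 8 genes called in both tissues. Some of the genes that this rule selects are not reported here.

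Alternatives fixed at the same time were DESeq2 size factors, upper quartile scaling, library size alone, no filter, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, all 12 libraries in 1 model, a 2-fold threshold and leaving out each library in turn. After the data were seen, further alternatives were added: the log2 ratio of counts in genes without to genes with an opposite exon as a term of the model, both classes of genes fitted apart, lists of features opposite the members of each list, and overlap of calls made without mutant ovary replicate 2. The Y, X window and Su(Ste) summaries were also chosen after the values were seen. X windows were 1, 2.5 and 5 Mb to each side of Tdrd5l. Random sets of features were drawn 10000 times.

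The fits were tested on simulated data with the fitted noise and 200 genes changed by 2-, 4- or 16-fold. In testes edgeR recovered 10.9%, 85.9% and 100% of these with 6 false calls, in ovaries 0%, 11.3% and 80.4% with 2 false calls, and for the interaction 1.59%, 6.06% and 42.2% with 1 false call. DESeq2 made 33 false calls in simulated ovaries, 29.7% of its calls there, and 13 in testes. With a dispersion of 0.02 edgeR recovered 82.3%, 100% and 100% in testes, 75.4%, 100% and 100% in ovaries and 19.0%, 47.8% and 78.8% for the interaction. Camera and fry each called a list shifted 2-fold in both tissues and 0 other lists. The simulated genes were drawn independently, so this cannot show false list calls that come from correlated members. In the data the estimated correlation was 0.66 for spermatid differentiation genes in testes and 0.96 for ribosomal protein genes in ovaries. Genes were also tested under the 10 splits of 6 libraries and under 100 drawn splits for the interaction. Computations used R 4.3.3, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.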

Results

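RNA-seq gene counts were compared between Drosophila melanogaster gonads mutant for Tdrd5l, which encodes a Tudor domain protein, and gonads of a control line called cas9 iso in the labels. Testes came from males 1 to 2 days old and ovaries from females 0 to 1 day old. Testis RNA was depleted of ribosomal RNA and ovary RNA was poly(A) selected, so RNA selection went with tissue. Each of the 4 groups held 3 libraries, called biological replicates in the labels. Gene counts totalled 2880119, 2742831 and 1641828 in mutant testis libraries 1, 2 and 3 and 1390699, 1691857 and 2228627 in the control testis libraries. The mutant ovary libraries held 908980, 1647933 and 912974 and the control ovary libraries 969812, 841428 and 772292. Between 12706 and 13656 genes had counts in a testis library and between 8345 and 10418 in an ovary library. The 12 replicate pairs all differed by more than counting noise (chi-square per degree of freedom 4.31 to 50.6), and each library was counted as 1 sample.

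Antisense RNAs held more counts than the protein-coding genes they lie across. In control ovaries asRNA:CR45874 had 159426 counts and RpS9, the ribosomal protein gene on the other strand, had 276. The antisense RNA asRNA:CR44020 had 8510 counts there and osk, the posterior determinant it overlaps, had 172. Of the 309 antisense RNAs with at least 50% of their exon bases opposite another gene, 270 pairs had enough counts in control ovaries, and in 237 of these (87.8%) the antisense RNA was denser per kilobase, with a median log2 ratio of 6.40. In control testes this held for 213 of 303 pairs (70.3%), with a median log2 ratio of 2.23. Genes held 3.33% to 5.02% of the uniquely aligned records in testis libraries and 1.95% to 3.29% in ovary libraries. The library kit named in the labels does not mark strand and the counting setting is not given in the sources used here. Values of genes with an exon opposite another gene are therefore uncertain throughout, and how far the counts of the other genes reflect their RNA was not measured. Genes without an opposite exon held 37.1% ± 8.63 (SD, n = 3) of the counts in mutant testes and 34.1% ± 3.81 (SD, n = 3) in control testes (exact two-sided permutation p = 0.7, where 3 against 3 libraries allow no p below 0.1). The shares were 17.0% ± 13.5 (SD, n = 3) in mutant ovaries and 13.4% ± 3.74 (SD, n = 3) in control ovaries (exact two-sided permutation p = 1). Mutant ovary replicate 2 stood apart at 32.5%, against 8.90% to 17.6% in the other ovary libraries.

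**Figure D1:**
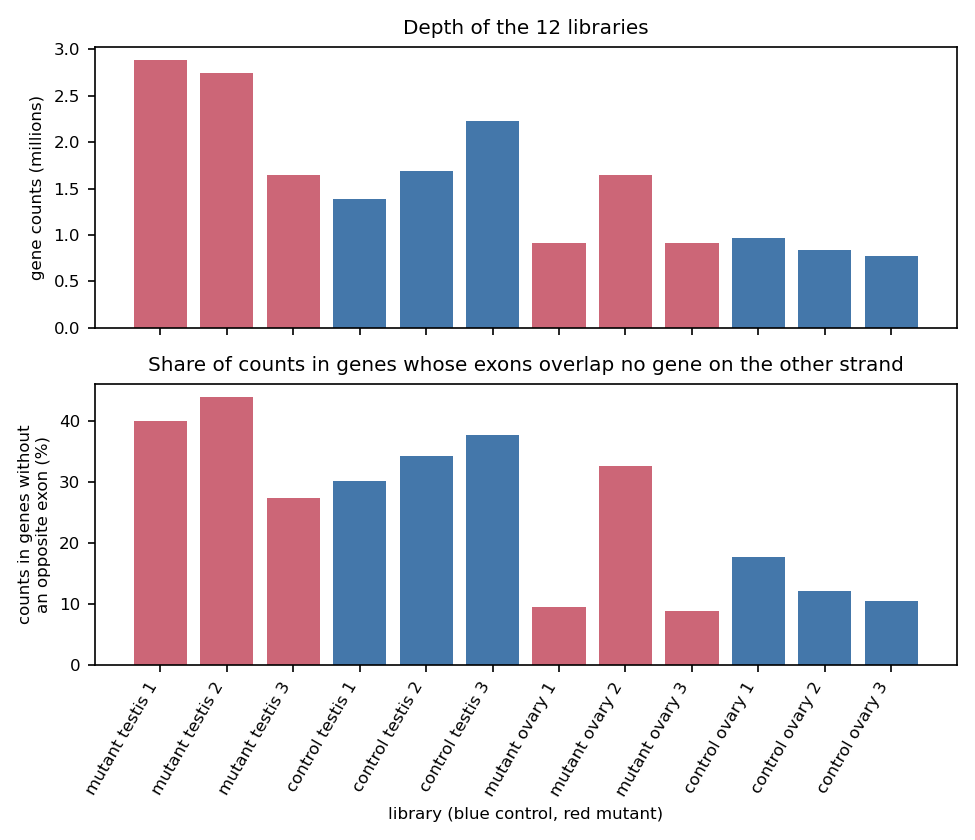
Gene counts and the percent of counts in genes without an opposite exon, one mark per library, with mutant libraries in red and control libraries in blue. Mutant ovary replicate 2 lies at 32.5% and 1647933 counts, above the other ovary libraries on both axes, and mutant testis replicate 3 has the lowest share of the testis libraries (27.4%).

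Tdrd5l counts did not differ detectably between the genotypes in either tissue. Tdrd5l (listed as CG15930, FBgn0029754, X chromosome 5315130 to 5317295, minus strand) had 938, 739 and 679 counts in mutant testis libraries 1, 2 and 3 and 542, 549 and 684 counts in the control testis libraries. Relative to library totals these were 336 ± 72.6 CPM (counts per 1000000) in mutant and 340 ± 43.6 CPM in control testes (SD, n = 3 each; exact two-sided permutation p = 1). The log2 fold change in testes was 0.01 (SE 0.34, edgeR adjusted p = 0.998) and lay between -0.31 and 0.21 over the alternative settings. In ovaries the gene had 12, 8 and 11 counts in mutant and 9, 4 and 6 counts in control libraries, below the filter on low counts. The ovary levels were 10.035 ± 4.52 CPM in mutant and 7.27 ± 2.30 CPM in control libraries (SD, n = 3 each; exact two-sided permutation p = 0.4). The labels do not describe the lesion, and a count of the whole gene does not check the genotype labels. Of the Tdrd5l exon bases 3.24% lie opposite CG4198, and how far these counts reflect Tdrd5l RNA was not measured.

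The first comparison asked which genes differ between mutant and control testes. Traf4, an adaptor of tumour necrosis factor receptor signalling, rose from 3.48 ± 1.15 to 441 ± 149 CPM (SD, n = 3 each) in mutant testes. CG42700 rose from 65.6 ± 22.5 to 1072 ± 421 CPM. Osi14, a member of the Osiris family, fell from 63.0 ± 8.77 to 1.38 ± 0.936 CPM, and dUTPase, which removes dUTP from the nucleotide pool, fell from 229 ± 56.3 to 7.83 ± 1.16 CPM. In all, 92 of 9768 tested genes passed (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted), 31 higher and 61 lower in mutant testes, each by at least 2-fold. The 6 libraries separated the genotypes without overlap for 1152 genes, 11.8% of those tested, where 10% is the share given by chance.

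Among the rises, Traf4 (FBgn0026319, 2L 4361925 to 4380716) had a log2 fold change of 6.99 (edgeR adjusted p = 5.22e-13). CG5937 (FBgn0029834, X 6040005 to 6050381) had 2 counts over the control libraries and 220 over the mutant libraries, a ratio of 80.4 (95% counting interval 22 to 668; edgeR adjusted p = 1.77e-07). The antisense RNA asRNA:CR44958 (FBgn0266263, X 5680627 to 5682127) had 3 and 153 counts, a ratio of 37.3 (12.5 to 183; edgeR adjusted p = 1.50e-05). Mst36Fb, a gene named for male-specific transcripts, went from 0.835 ± 0.868 to 25.8 ± 8.36 CPM (log2 4.74, edgeR adjusted p = 1.30e-05). CG42700 (FBgn0261611, 2R 12279771 to 12300795, opposite CG8850) had a log2 fold change of 4.03 (edgeR adjusted p = 8.24e-09). The noncoding lncRNA:CR45577 had 0 control counts and 67 mutant counts, at least 16.3-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.00130). Such intervals and floors cover counting error only. The other largest rises were lncRNA:CR45791 (log2 4.47, edgeR adjusted p = 2.46e-04), lncRNA:CR44206 (4.20, 0.00278), lncRNA:CR45020 with 3 and 73 counts (ratio 17.8, 5.85 to 88.3; 0.0104) and CG3397 (3.54, 0.0465).

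Among the falls, Osi14 (FBgn0040279, 3R 6299128 to 6300738) had a log2 fold change of -5.59 (edgeR adjusted p = 1.89e-09) and dUTPase (FBgn0250837, 2L 11011312 to 11012135) of -4.87 (edgeR adjusted p = 9.10e-11). All dUTPase exon bases lie opposite asRNA:CR45778, which had 1609 raw counts in control and 2197 in mutant testes, where dUTPase had 1165 and 57. The mutant testis libraries held more gene counts on average, so these sums do not show a rise of the antisense RNA. Which strand the counts of this pair reflect is uncertain, and so is a fall of dUTPase RNA. CG6414 (FBgn0029690, X 3968788 to 3971350, opposite asRNA:CR45481) fell from 70.1 ± 21.0 to 2.83 ± 0.843 CPM (edgeR adjusted p = 7.95e-09), and CG14420 (FBgn0029643, X) from 60.5 ± 11.1 to 2.40 ± 2.40 CPM (edgeR adjusted p = 1.59e-07). CG13248 had 57 control and 2 mutant counts, 39.0 times fewer (10.3 to 330; edgeR adjusted p = 0.00213). The Y-linked repeat copy Su(Ste):CR42424 had 46 and 2 counts, 31.5 times fewer (8.23 to 268; edgeR adjusted p = 0.0120). The remaining large falls were TotB, a secreted stress factor of the Turandot family (log2 -4.30, edgeR adjusted p = 0.00392), CG32187 (-4.23, 0.00238), CG12075 (-4.13, 0.00312) and lncRNA:CR44957 (-4.02, 7.59e-04).

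**Figure D2:**
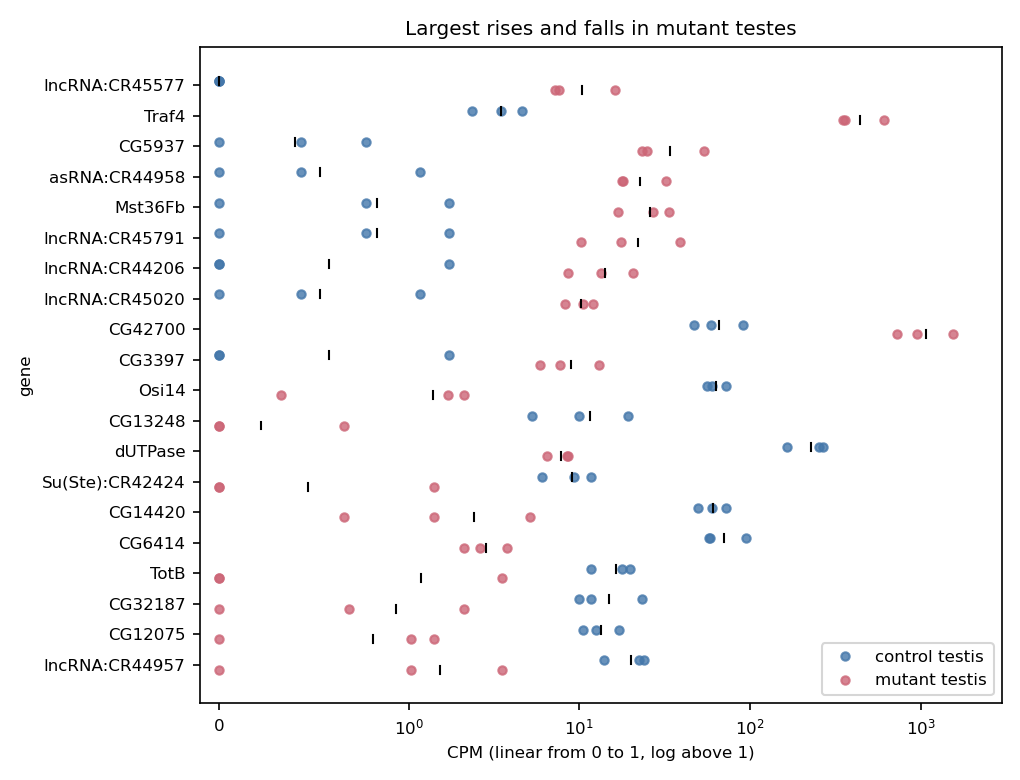
CPM in each testis library for the 10 largest rises and 10 largest falls, with mutant libraries in red, control libraries in blue and black ticks at the group means; the axis is linear from 0 to 1 and logarithmic above. The 3 mutant libraries do not overlap the 3 control libraries in any of these genes, as the rule for choosing them required; Traf4 has the largest mutant mean after CG42700 (441 and 1072 CPM).

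Of the 25 called genes that the fixed rule named in testes, 8 passed in every alternative setting, namely Traf4, CG5937, asRNA:CR44958, CG42700, Osi14, dUTPase, CG14420 and CG6414. Their highest adjusted p over the alternatives was 0.0325, for asRNA:CR44958. Single libraries decided the call of 7 of the 20 largest changes. Without mutant replicate 2, lncRNA:CR45020, CG12075 and TotB had edgeR adjusted p = 0.126, 0.0520 and 0.0710, within ranges over the alternatives that reached 0.358, 0.142 and 0.587. Without control replicate 1, CG13248 and CG32187 had edgeR adjusted p = 0.1003 and 0.0833 (up to 0.1003 and 0.323 over the alternatives) and lncRNA:CR45020 had 0.0629. CG3397 lost its call in 9 of 16 alternatives, among them limma-voom (0.0547), library size alone (0.158) and the fits without mutant replicate 1 (0.526), mutant replicate 2 (0.144), control replicate 1 (0.257) or control replicate 2 (0.273). Su(Ste):CR42424 lost it in 6 of 16, among them library size alone (0.0560) and the fits without mutant replicate 1 (0.0985), mutant replicate 2 (0.216), control replicate 1 (0.0852) or control replicate 2 (0.153). TotB also lost its call with DESeq2 (0.543). The count of 92 genes became 49 without mutant replicate 2, 52 without control replicate 1 and 725 without mutant replicate 3. It was 58 with library size alone as the scaling and 9 with all 12 libraries in 1 model.

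RNA regulators of the female germline, named in the series title, were read in testes as well. The counts of grk (39.9 ± 13.9 CPM in control and 19.4 ± 7.58 CPM in mutant testes, SD, n = 3 each; log2 -1.06, edgeR adjusted p = 0.371) and nanos (1038 ± 138 and 759 ± 338 CPM; -0.45, 0.856) did not pass over the 6 libraries. Without mutant replicate 3 both passed, with edgeR adjusted p = 0.0128 for grk and 0.0253 for nanos. That fit called 725 genes. Genes without an opposite exon then held 40.0% and 43.9% of counts in the mutant libraries and 30.1% to 37.7% in the control libraries. Genotype therefore cannot be told apart from the strand share in that fit. With the strand share as a term, chosen after seeing the data, neither grk nor nanos passed. The log2 fold changes of orb, bru1, bcd, me31B and tral lay between -0.09 and 0.16 (edgeR adjusted p = 0.961 to 0.995), and osk was below the filter in testes. The doublesex gene dsx, which directs somatic sex, had 67.2 ± 8.85 CPM in control and 30.1 ± 11.5 CPM in mutant testes (log2 -1.17, edgeR adjusted p = 0.154; 0.00194 without mutant replicate 3). With the strand share as a term dsx passed (edgeR adjusted p = 0.0268).

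Gene groups fixed before the data were examined were then tested in testes. Genes of spermatid differentiation and the post-meiotically transcribed cup and comet genes were higher in mutant testes as groups, and so were cytoplasmic ribosomal protein genes. Immune genes and mitochondrially encoded genes were lower as groups. Of the 27 groups with enough members, these 5 passed with camera at the preset correlation of 0.01, and 0 passed with an estimated correlation or with fry. Spermatid differentiation genes were higher in 24 and lower in 2 of 26 members (median log2 0.34, camera adjusted p = 0.0152; adjusted p = 0.861 with an estimated correlation, range over alternatives 2.8e-06 to 0.861). Examples are the sperm tail genes Mst84Dd (846 ± 129 and 1594 ± 292 CPM; log2 0.91) and Mst84Dc (0.71), and 0 members passed singly over all genes or adjusted over the list alone. Without mutant replicate 3, a fit that called 725 genes, Mst84Dd and Mst84Dc passed (edgeR adjusted p = 0.00477 and 0.0141). Mst84Dd also passed with the strand share as a term (edgeR adjusted p = 2.4e-04). All 13 tested cup and comet genes were higher (median 0.49, camera adjusted p = 0.0152; adjusted p = 0.861 with an estimated correlation, range 1.3e-04 to 0.861), among them p-cup (log2 0.76) and sunz (0.71), with 0 members passing singly on either count. In the fit without mutant replicate 3 p-cup and sunz passed (edgeR adjusted p = 0.0336 and 0.0454). Ribosomal protein genes were higher in 64 and lower in 20 of 84 members (median 0.18, camera adjusted p = 0.0463; adjusted p = 0.861 with an estimated correlation, range 0.00211 to 0.861), with 0 members passing singly on either count.

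Antimicrobial peptide and immune genes were lower in 5 and higher in 1 of 6 members (median -0.45, camera adjusted p = 0.0124; adjusted p = 0.861 with an estimated correlation, range over alternatives 0.00110 to 0.861). The stress factor TotA (FBgn0028396) fell from 45.0 ± 8.75 to 9.89 ± 3.61 CPM (log2 -2.20, edgeR adjusted p = 0.00130), and 2 members were lower when adjusted over the list alone. Mitochondrially encoded genes were lower in 10 and higher in 1 of 11 members (median -0.24, camera adjusted p = 0.0438; adjusted p = 0.861 with an estimated correlation, range 2.4e-05 to 0.861). The complex I subunit gene mt:ND6 fell from 50.3 ± 31.3 to 16.7 ± 4.25 CPM (log2 -1.59, edgeR adjusted p = 0.0475), and 2 members were lower adjusted over the list alone. The mt:ND6 call ended in 10 of 17 alternatives, among them DESeq2 (0.0530), limma-voom (0.125), all 12 libraries in 1 model (0.869) and the fits without control replicate 1 (0.932), mutant replicate 1 (0.0505) or mutant replicate 2 (0.367). Single libraries also decided the group calls. Without control replicate 1, 0 groups passed, with camera adjusted p = 0.249 for spermatid and for cup and comet genes, 0.303 for ribosomal protein genes, 0.0660 for immune genes and 0.707 for mitochondrial genes. Without mutant replicate 2, 1 group passed, and the 5 groups had 0.222, 0.118, 0.264, 0.0858 and 0.0541 in that order. Without mutant replicate 1 the first 3 had 0.348, 0.278 and 0.348. Without control replicate 2 the spermatid genes had 0.0622 and the ribosomal protein genes 0.144, and the mitochondrial genes had 0.0678 without mutant replicate 3 and 0.0634 without control replicate 3. With the strand share of the libraries as a term, chosen after seeing the data, the medians were 0.17 for spermatid genes (camera adjusted p = 0.136), 0.26 for cup and comet genes (0.0483), 0.05 for ribosomal protein genes (0.259), -0.43 for immune genes (0.0483) and -0.32 for mitochondrial genes (0.136). Mutant testis replicate 3 lay apart from the other mutant testis libraries, with medians among genes without an opposite exon of -1.10 for spermatid genes, -1.26 for cup and comet genes and -0.53 for all genes (log2). The mean log2 CPM of spermatid genes was 8.52 in that library, below all 3 control libraries (8.68, 8.88 and 9.04), and 9.51 and 9.46 in mutant replicates 1 and 2. The medians of the 5 groups kept their sign under every scaling, which moved the median of all testis genes between -0.01 and 0.03.

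The other 22 groups tested in testes did not pass as groups. Y-linked male fertility genes were lower in 6 and higher in 3 of 9 members (median log2 -0.26, camera adjusted p = 0.140). Among them kl-2 (FBgn0001313, Y 573088 to 664173), an axonemal dynein heavy chain gene of the sperm flagellum, fell from 130 ± 15.2 to 30.8 ± 2.07 CPM (log2 -2.08, edgeR adjusted p = 1.92e-04), and 1 member passed adjusted over the list alone. That group passed without mutant replicate 1 (0.0129), mutant replicate 2 (0.00197) or control replicate 3 (0.0359) and with the strand share as a term (median -0.97, 0.0483), and its adjusted p reached 0.861 over the alternatives. DNA damage and p53 target genes were split 5 to 5 (median -0.06, 0.230), and Corp, a p53 target (FBgn0030028), fell from 86.3 ± 22.1 to 13.6 ± 8.82 CPM (log2 -2.73, edgeR adjusted p = 1.32e-04), the 1 member passing adjusted over the list alone. Maternal RNA localization and translation regulators were split 12 to 10 (median 0.01, -0.03 with upper quartile scaling; camera adjusted p = 0.734). Of these, png, a kinase gene needed at egg activation (FBgn0000826), rose from 3.55 ± 3.64 to 19.2 ± 8.63 CPM (log2 2.52, edgeR adjusted p = 0.0294) and was the 1 member passing adjusted over the list alone. The png call ended in 7 of 17 alternatives, among them library size alone (0.124), limma-voom (0.167), all 12 libraries in 1 model (0.857) and the fits without mutant replicate 2 (0.176), control replicate 2 (0.183) or control replicate 3 (0.0824).

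Neuronal markers were lower in 6 of 7 (median -0.66, camera adjusted p = 0.0540), with elav at log2 -0.90. Accessory gland and ejaculatory duct markers were higher in 10 of 14 (0.33, 0.230), and that group passed without mutant replicate 1 (0.0129), mutant replicate 3 (0.0496), control replicate 2 (0.0130) or control replicate 3 (0.0167), with a highest adjusted p of 0.861 over the alternatives. Muscle markers were lower in 13 of 16 (-0.13, 0.270), somatic cyst and hub cell markers higher in 6 of 9 (0.26, 0.443) and gut markers lower in 3 of 4 (-0.20, 0.734; 1 higher and 1 lower adjusted over the list alone). Fat body markers (median 0.08, mean -0.04; 0.784), hemocyte markers (median 0.04, mean -0.10; 0.745) and ovarian follicle stem and stalk cell markers (-0.36, 0.784) did not pass. Germline groups gave small medians: testis stem cell and spermatogonial genes -0.10 (0.549), tTAF and tMAC transcription regulators 0.27 (0.689), meiotic division genes 0.27 (0.734), piRNA pathway genes -0.08 (0.734) and nurse cell and oocyte meiosis genes -0.06 (0.734). Tudor domain genes had -0.10 (0.734), maternal axis patterning genes -0.20 (0.262), and sex determination genes -0.10 (0.443; 1 lower adjusted over the list alone, dsx). P-body and mRNA decay genes had a median of -0.02 (0.01 with library size alone; mean 0.04; 0.929). Heat shock genes had a median of 0.05 and a mean of -0.03 (0.734), and oxidative and xenobiotic stress genes a median of 0.15 (0.443). In the groups of this paragraph other than gut and sex determination genes, 0 members passed over all genes or adjusted over the list alone. Among their named members, elav (edgeR adjusted p = 0.0106), pip (0.0104), grk and nanos passed in the fit without mutant replicate 3. Stellate genes (13 features) and replication-dependent histone genes (111 features) had 0 counts in testes, and chorion genes (2 tested), vitelline membrane genes (1) and yolk protein genes (1) had too few members for a test. Gene counts leave out records aligned to several places, so the 0 counts do not show that Stellate or histone genes were silent in either genotype.

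The called genes of testes were unevenly spread over the chromosomes, a pattern chosen for report after the values were seen. Of 36 tested Y-linked genes 13 passed, all lower in mutant testes. These were kl-2 and 12 copies of Su(Ste), the Y-linked repeats whose small RNAs silence the X-linked Stellate genes. All 22 tested Su(Ste) copies were lower (median log2 -1.59, quartiles -1.95 and -1.24; -1.62 to -1.59 over the scalings). Their summed level was 3640 ± 797 CPM in control and 1433 ± 658 CPM in mutant testes (SD, n = 3 each), a log2 ratio of -1.35 with no overlap of the groups (exact two-sided permutation p = 0.1, the smallest possible). The copies are near-identical, so counts of single copies are uncertain and the copies are not independent genes. The number of called copies was 4 without mutant replicate 1, 0 without mutant replicate 2, 19 without mutant replicate 3, 2 without control replicate 1 and 8 without control replicate 2, with every tested copy lower each time (medians -1.99 to -1.33). The summed level of the 9 Y-linked fertility genes was 244 ± 27.2 CPM in control and 131 ± 47.3 CPM in mutant testes (exact two-sided permutation p = 0.1), of which kl-2 alone held 130 and 30.8 CPM. The 5 other tested Y-linked features had a median log2 fold change of 0.28. On the X chromosome 24 of 1414 tested genes passed (1.70%, against 0.814% elsewhere; two-sided Fisher's exact test, adjusted p = 0.0121 over 9 chromosome classes). On 2R 4 of 1957 passed (0.204%, against 1.13% elsewhere, a share that includes the Su(Ste) copies; adjusted p = 1.46e-04). Within 2.5 Mb of Tdrd5l 12 of 263 X-linked genes passed (4.56%), against 12 of 1151 (1.04%) on the rest of the X chromosome (two-sided Fisher's exact test, p = 4.35e-04). With windows of 1 and 5 Mb the p was 0.0222 and 0.0116. With the strand share as a term 5.32% passed within 2.5 Mb, 1.04% on the rest of the X chromosome and 1.59% on the autosomes.

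**Figure D3:**
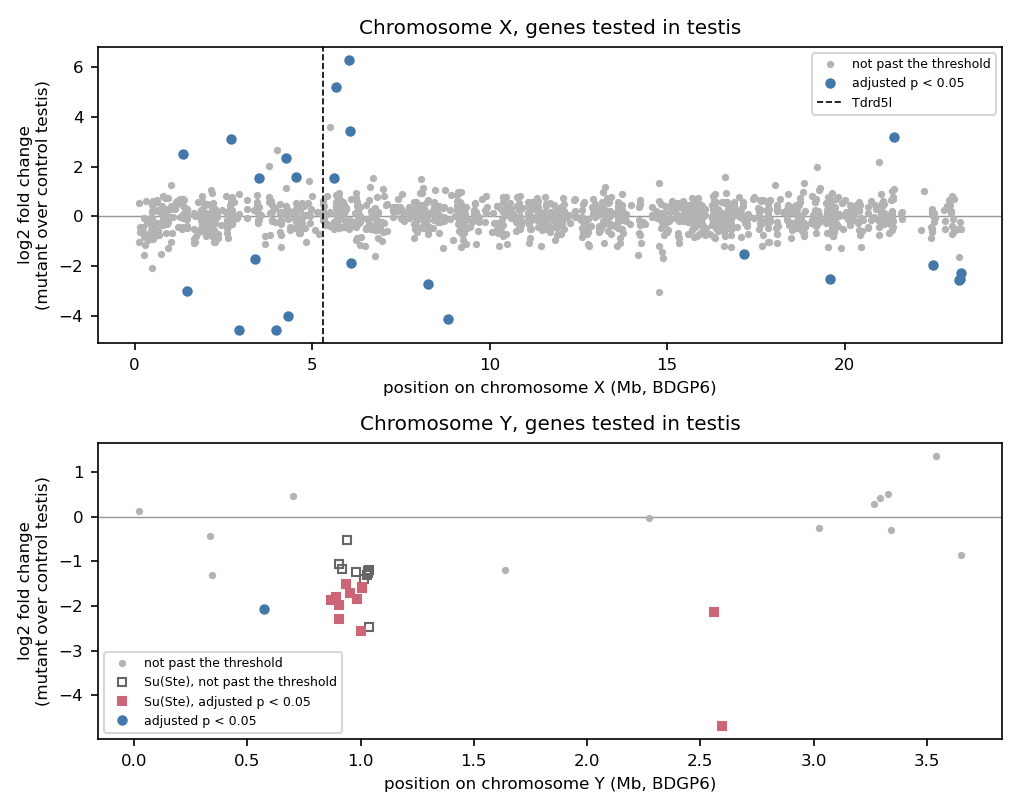
Log2 fold change in mutant against control testes by position in Mb on the X chromosome, with a dashed line at Tdrd5l, and on the Y chromosome, with Su(Ste) copies as squares. Called genes gather around the dashed line, with 12 of 263 within 2.5 Mb, and the 22 Su(Ste) squares all lie below 0.

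The second comparison asked which genes differ between mutant and control ovaries. No gene passed the test over all 6 ovary libraries, and counts of several maternal genes named beforehand differed widely among the 3 mutant libraries. Counts of osk stood at 61.7 ± 33.9 CPM in control and 238 ± 319 CPM in mutant ovaries (SD, n = 3 each; log2 1.95). The antisense RNA asRNA:CR44020, which overlaps osk, had far more counts, so how far these values reflect osk RNA is uncertain. Those of grk, the dorsal-ventral signal of the oocyte, stood at 255 ± 38.5 CPM in control and 158 ± 50.6 CPM in mutant ovaries, with no overlap between the groups (log2 -0.70), and those of nanos at 78.2 ± 14.5 and 97.1 ± 22.7 CPM (0.31). The translation regulators orb, bru1, me31B and tral had log2 fold changes of 1.17, 1.62, 1.76 and 0.98, each with a mutant SD above the mutant mean, and bcd was below the filter. Mutant ovary replicate 2 stood apart here too. Maternal regulators without an opposite exon were a median of 3.23 log2 units higher in it than in its group mates. These 7 tested genes had edgeR adjusted p = 0.999. The piRNA pathway gene mael had 9.78 ± 0.694 CPM in control and 30.1 ± 10.4 CPM in mutant ovaries (log2 1.61, edgeR adjusted p = 0.980), and the pole plasm gene vls had 172 ± 10.6 and 273 ± 49.4 CPM (log2 0.66, edgeR adjusted p = 0.999). Of 4683 tested genes edgeR called 0 (184 had an unadjusted p under 0.05), DESeq2 called 14 and limma-voom 0. The genotypes did not overlap for 467 genes, 9.97% of those tested, where chance gives 10%.

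The genes with the smallest ovary p were teq, a serine protease gene (198 ± 43.0 CPM in control and 17.5 ± 5.13 CPM in mutant ovaries, log2 -3.48), and stops, a SOCS-box gene of photoreceptors (107 ± 16.4 and 3.67 ± 2.11 CPM, log2 -4.78), both with edgeR adjusted p = 0.0768. With upper quartile scaling 1 gene passed, stops (0.0469). With a filter at 1 CPM teq (0.0360), stops (0.0172) and lncRNA:CR45179 (0.0368) passed. With all 12 libraries in 1 model 5 genes passed, these 3 with CG31955 (0.0221) and asRNA:CR46047 (0.0333), the last pair chosen after their values were seen. Without mutant ovary replicate 2 the count was 55, 33 higher and 22 lower.

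Among ovary gene groups, ribosomal protein genes were higher in 78 of 78 members (median log2 1.42, camera adjusted p = 0.138), and 0 of the 19 tested groups passed with camera, with an estimated correlation or with fry. RpL30, for example, had 75.8 ± 59.5 CPM in control and 261 ± 339 CPM in mutant ovaries (log2 1.79, edgeR adjusted p = 0.999). Its group moved with 1 library: in mutant ovary replicate 2 the members without an opposite exon were a median of 4.50 log2 units higher than in its group mates. Without that library the group turned lower in mutant ovaries (camera adjusted p = 2.6e-05), and it was higher without mutant replicate 1 (1.3e-07), mutant replicate 3 (8.1e-10) or control replicate 1 (4.0e-07); its adjusted p reached 0.997 over the alternatives. Under upper quartile scaling 77 of 78 members were higher, and with the strand share as a term, chosen after seeing the data, the median was 0.00 (camera adjusted p = 0.435). Maternal RNA localization and translation regulators were higher in 16 of 18 (median 0.67, camera adjusted p = 0.582). That group passed without mutant replicate 1 (0.0136) or mutant replicate 3 (0.00102), with a highest adjusted p of 0.997 over the alternatives, and its members without an opposite exon were a median of 3.23 log2 units higher in mutant ovary replicate 2 than in its group mates. piRNA pathway genes were higher in 14 of 20 (0.54, 0.710), and muscle markers in 11 of 15 (median 0.35; tested lower, 0.710). Muscle markers passed as lower without mutant replicate 2 (2.6e-05) and, as the only ovary group, with the strand share as a term (median -0.70, 5.42e-04), heat shock genes passed as lower without it (0.0101), and fat body markers passed without mutant replicate 1 (0.0263) or mutant replicate 3 (0.0404). These 3 groups reached an adjusted p of 0.997 over the alternatives.

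The remaining ovary groups had camera adjusted p of 0.849 or more. Medians were 0.34 for mitochondrially encoded genes (7 of 11 higher), 0.60 for follicle stem and stalk cell markers (3 of 3), 0.48 for hemocyte markers (5 of 5) and 0.37 for P-body genes (8 of 10). They were 0.19 for axis patterning genes (6 of 8), 0.10 for nurse cell and oocyte meiosis genes (9 of 15), 0.28 for sex determination genes (7 of 10) and 0.20 for fat body markers (2 of 3). Medians lay above 0 while the test pointed lower for heat shock genes (0.21, 4 of 8 higher), testis stem cell and spermatogonial genes (0.27, 7 of 10), oxidative stress genes (0.27, 2 of 3), Tudor domain genes (0.19, 5 of 9; -0.02 with upper quartile scaling) and somatic cyst markers (0.15, 5 of 7; -0.09 with upper quartile scaling). DNA damage genes had a median of 0.11 (2 of 4 higher; -0.02 with library size alone) and accessory gland markers of -0.03 (2 of 4; 0.00 with DESeq2 size factors). The median of all ovary genes was 0.14 with TMM scaling, 0.17 with DESeq2 size factors, 0.06 with upper quartile scaling and 0.03 with library size alone. In these groups 0 members passed over all genes or adjusted over the list alone. Groups with fewer than 3 tested members were spermatid differentiation, cup and comet, and tTAF and tMAC genes (1 each), meiotic division, chorion, vitelline membrane, yolk protein, gut, neuronal and immune genes (2 each), and Y-linked fertility, Stellate and histone genes (0 each). Among them the yolk protein gene Yp1 had 16.1 ± 9.39 CPM in control and 106 ± 162 CPM in mutant ovaries (log2 2.72, edgeR adjusted p = 0.999).

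The difference of the mutant effect between the tissues was tested directly in all 12 libraries. The stops gene (FBgn0086704, 3R, opposite Gycbeta100B) had 113 ± 24.0 CPM in control and 3.53 ± 2.17 CPM in mutant ovaries (SD, n = 3 each), against 1.96 ± 1.16 and 5.86 ± 1.70 CPM in testes. The difference of its log2 fold changes, ovary minus testis, was -6.46 (edgeR adjusted p = 0.00387). CG6414 had 59.6 ± 26.2 and 87.9 ± 29.4 CPM in control and mutant ovaries and 66.9 ± 21.1 and 2.75 ± 0.904 CPM in testes, a difference of 5.07 (edgeR adjusted p = 0.00629). The noncoding lncRNA:CR45179 (FBgn0266689, 3L) had 1.73 ± 1.91 and 90.8 ± 35.6 CPM in control and mutant ovaries and 14.1 ± 3.18 and 15.3 ± 5.29 CPM in testes, a difference of 5.41 (edgeR adjusted p = 0.0393). These were the 3 genes that passed of 10321 tested, and 550 had an unadjusted p under 0.05. The next were dUTPase (5.70, 0.0650), CG5937 (-9.45, 0.102) and teq (-3.10, 0.161). The stops call held in all 18 alternatives (highest adjusted p = 0.0363). CG6414 lost its call without mutant testis replicate 2 (0.0780) or 3 (0.0622), and lncRNA:CR45179 lost it in 9 of 18 alternatives, with TMM within each tissue (0.0622) and without any 1 of the testis libraries or control ovary replicate 2 or 3 (0.0729 to 0.232). The count of 3 became 1 without mutant testis replicate 2 or 3, 6 without mutant ovary replicate 1 or 2 and 5 without mutant ovary replicate 3. RNA selection went with tissue, so a difference between tissues can come from either.

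Changes shared by the tissues were sought among the 4223 genes tested in both. Of these 20 were called in testes and 0 in ovaries, so 0 could be shared and Fisher's exact test cannot show whether changes are shared. The log2 fold changes had Pearson r = 0.12 and Spearman rho = 0.11 across genes, which are not independent replicates. With DESeq2's calls, 22 in testes and 10 in ovaries, 2 genes were shared (0.0521 expected of independent lists; Fisher p = 0.00114), CG31955 lower (log2 -2.65 in testes and -3.13 in ovaries) and asRNA:CR46047 higher (1.85 and 4.92). In simulated ovaries with the fitted noise 29.7% of DESeq2's calls were false, so its ovary calls are less certain. With the ovary calls made without mutant ovary replicate 2, CG31955, CG2818, lncRNA:CR45791 and asRNA:CR46047 were shared, 4 where 0.223 were expected (Fisher p = 5.76e-05). Apart from lncRNA:CR45791, these genes were chosen after their values were seen.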

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

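All tests weighed here, apart from the splits of the samples and the interaction itself, were chosen only after the result was seen. A difference between the tissues, tested as the interaction, picked out 3 genes. The mutant effect in ovary minus testis was -6.46 (log2) for stops, 5.07 for CG6414 and 5.41 for lncRNA:CR45179. Of 100 splits 7, counting the real grouping, gave as many calls, with up to 115 calls in another split, so chance cannot be excluded for the count of 3. Splits that kept real genotype groups were not left out. The split with 7 calls kept the real groups of both tissues and swapped the ovary labels, and the split with 4 calls kept the real testis groups. RNA selection differed with tissue and remains a technical explanation beside a biological one.

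Antisense RNAs were denser than the genes they lie opposite to, by a median log2 ratio of 6.40 in control ovaries. Reads without strand would give both features of a pair similar density where they overlap, so that value speaks against this explanation. Genes counted on their own strand would hold most uniquely aligned records, and they held at most 3.29% in ovaries. Features opposite ribosomal protein genes had a median percentile of 90.4 in control ovaries against 70.8 for other features with an opposite exon (one-sided permutation p = 0.0012), as if counts followed the gene on the other strand, and mutant ovaries gave 91.1 against 69.5 (p = 0.0002), but control testes gave 72.3 against 64.5 (p = 0.232) and mutant testes 75.5 against 63.5 (p = 0.106). In control ovaries the lower quartile of the log2 ratio was 2.68. For ovaries these values argue against reads without strand and against counting on the own strand. They go with counts that follow the gene on the other strand, for which testes gave no clear difference. The kit named does not mark strand, and why counts would follow the other strand was not tested. A biological excess of antisense RNA, counted on its own strand, would also place most uniquely aligned records in features. Records without a feature made up 96.6% to 98.0% of these in ovary libraries, which argues against such an excess as the whole account there. In testes it was not excluded, and no separate measurement of antisense RNA was made.

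Mutant ovary replicate 2 held 32.5% of its counts in genes without an opposite exon. Maternal regulators without an opposite exon were higher than in the group mates by a median log2 ratio of 3.23, but so were muscle markers (3.37) and all genes without an opposite exon (2.51), so RNA of another tissue was not excluded. Genes rose against their antisense RNAs by a median of 1.78 (151 of 167 higher), which is consistent with a less one-sided counting of strands in that library. A biological difference of this sample, such as the stage of its egg chambers, was not tested.

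Su(Ste) copies were lower in mutant testes. Whether Y-linked RNA was lower more widely stays open: the fertility genes had a median log2 fold change of -0.26, and -0.97 with the strand share as a term, while the 5 other Y-linked features had a median of 0.28. Counts moved between the tested copies would leave the sum unchanged, and it changed by a log2 ratio of -1.35; records aligned to several places, which gene counts leave out, were also fewer in mutant testes (14.77% to 16.63% against 18.82% to 20.4%), and how many came from these copies was not tested. With the strand share as a term the median of the Su(Ste) copies was -1.41. A different Y chromosome in the control stock and an effect of the mutation both stay possible.

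With 3 against 3 libraries the 10 splits of the samples are too few for a share under 0.05. In testes 2 of 10 splits gave as many called genes as the real 92, counting the real split, and the highest other gave 247. That split puts mutant replicates 1 and 2 with control replicate 3, the libraries with the largest shares of counts in genes without an opposite exon, and points to a structure of the samples. For testis lists 3 of 10 splits gave as many as the real 5 (highest other 6). In ovaries 10 of 10 splits gave as many genes as the real 0 (highest other 0) and 10 of 10 as many lists (highest other 4). Every split reaches a real count of 0, so these shares cannot test the ovary results.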

How the results depend on the processing

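Of the testis values of named genes 1214 stayed on their side of the threshold under the alternatives, 55 lost and 14 gained a call, and the sign changed in 25. For testis lists these were 228, 33 and 9, with 26 changes of sign. Of the 898 ovary values of the genes named for ovaries, which leave out stops, teq and lncRNA:CR45179, 0 passed and 49 changed sign, 23 of them without mutant ovary replicate 2. Of the ovary list values 179 stayed on their side, with 10 gains, 1 reversal of a call and 36 changes of sign. For the interaction 85 stayed, 11 were lost and 12 gained, with 0 changes of sign. The cause was not tested for any of these changes. Testis called genes (92) became 58 with library size alone, 9 with all 12 libraries in 1 model and 49 to 725 in leave-one-out. The alternatives chosen after seeing the data gave 177 with the strand share as a term, 22 among genes with an opposite exon alone and 28 among genes without, where the fit of all genes called 24 and 67. Testis lists (5) became 0 with an estimated correlation, 0 with fry, 3 with the strand share as a term and 0 to 6 in leave-one-out. Ovary called genes (0) became 1 with upper quartile scaling, 7 without a filter, 3 with the filter at 1 CPM, 14 with DESeq2, 5 with all 12 libraries, 0 to 55 in leave-one-out, 92 with the strand share as a term and 10 among genes with an opposite exon alone. Ovary lists (0) became 1 with the strand share as a term (muscle markers, lower) and 0 to 4 in leave-one-out. Cytoplasmic ribosomal protein genes in ovaries turned lower without mutant ovary replicate 2 (camera adjusted p = 2.6e-05; 8.1e-10 to 0.983 in leave-one-out). Interaction genes (3) became 5 with DESeq2 size factors, 6 with limma-voom, 13 with the strand share as a term and 1 to 6 in leave-one-out. Genes shared by the tissues (0) became 2 with DESeq2, 8 with the strand share as a term and 4 with ovary calls without mutant replicate 2. Ovary depth of 772292 to 1647933 gene counts left 4683 genes for testing.

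Replicate numbers did not pair the libraries, since no library correlated best with its own number (r from -0.53 to 0.28). With the number as a block, called genes were 79 in testes and 0 in ovaries, lists 3 in testes (spermatid and cup and comet genes with 0.0507 and ribosomal protein genes with 0.112 lost, accessory gland markers with 0.0199 gained) and 0 in ovaries, the interaction gave 6 genes and 0 genes were shared. The cause was not tested.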

Other observations

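With the strand share of each library as a term, chosen after seeing the data, 92 ovary genes passed, 44 higher and 48 lower. The genes given here were chosen after their values were seen. The serine protease gene teq (198 ± 43.0 CPM in control and 17.5 ± 5.13 CPM in mutant ovaries, SD, n = 3 each; log2 -3.51, edgeR adjusted p = 4.34e-04) and stops (107 ± 16.4 and 3.67 ± 2.11 CPM; -4.75, 4.34e-04) fell. The testis-type cytochrome c gene Cyt-c-d fell from 760 ± 69.0 to 294 ± 83.9 CPM (-1.37, 0.00208), and CG31955 from 165 ± 36.1 to 18.4 ± 10.5 CPM (-3.18, 0.00590). The condensin subunit gene Cap-H2 rose from 194 ± 26.2 to 436 ± 92.9 CPM (1.20, 0.00753), as did asRNA:CR45016 opposite to it (274 ± 29.6 to 1656 ± 773 CPM; 2.53, 4.34e-04), CG6661 (44.1 ± 9.72 to 234 ± 111 CPM; 2.39, 4.34e-04) and lncRNA:CR45179 (1.72 ± 1.95 to 88.7 ± 19.6 CPM; 5.47, 0.00110). Exon bases of Cyt-c-d lie opposite CG31808, those of CG6661 opposite asRNA:CR42871 and those of stops opposite Gycbeta100B. Which gene of each pair these counts reflect is uncertain, as it is for Cap-H2 and asRNA:CR45016.

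Further called testis genes, chosen after their values were seen, include the polarity gene baz (10374 ± 2359 CPM in control and 3634 ± 1353 CPM in mutant testes, SD, n = 3 each; log2 -1.51, edgeR adjusted p = 0.0313), the noncoding lncRNA:CR45998 (40.8 ± 8.73 and 371 ± 87.3 CPM; 3.18, 1.77e-07) and the ribosomal RNA pseudogene 28SrRNA-Psi:CR40741 (10524 ± 4411 and 1823 ± 621 CPM; -2.53, 1.42e-04). Exon bases of baz lie opposite TTLL1A and those of lncRNA:CR45998 opposite lncRNA:CR43949. Which gene of each pair these counts reflect is uncertain, and so is a fall of baz RNA. With the strand share as a term the pseudogene kept its log2 fold change (-2.53) but not its call (edgeR adjusted p = 0.259). Testis RNA was depleted of ribosomal RNA, and whether the pseudogene counts reflect ribosomal RNA left after depletion was not tested. Records aligned to several places also differed between the genotypes without overlap, so a difference in RNA preparation was not excluded.

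Features opposite the maternal regulators were also read in ovaries, a test chosen only after the result was seen. All 8 were higher in mutant ovaries (median log2 0.50, camera adjusted p = 0.0155 over 13 sets; adjusted p = 0.713 with an estimated correlation), among them asRNA:CR44020 opposite osk (3334 ± 1007 and 6512 ± 2729 CPM; log2 0.97, and 1.01 with edgeR adjusted p = 0.00590 with the strand share as a term). With the strand share as a term 7 of the 8 were higher (median 0.52, camera adjusted p = 9.7e-04, and 0.607 with an estimated correlation). In testes 3 of 7 such features were higher (median -0.11, camera adjusted p = 0.942). Such features can overlap the maternal gene over a small part only. Of the exon bases of asRNA:CR44020 19.76% lie opposite osk, and of those of CG11779 9.12% lie opposite nanos. How far counts of these features reflect the maternal RNAs was not measured, and the call ends with the estimated correlation. Whether maternal RNAs differ between the genotypes therefore stays open.

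Called testis genes gathered near Tdrd5l on the X chromosome (Fisher p = 4.35e-04 for the window of 2.5 Mb, chosen after the result was seen). X chromosomes of different origin around Tdrd5l could give this pattern, and their sequence was not tested. In ovaries, with the strand share as a term, 4 of 147 genes in the window and 15 of 721 on the rest of the X chromosome passed (Fisher p = 0.546).

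With the strand share as a term, chosen after the result was seen, 8 genes were called in both tissues, all in the same direction, where 0.975 were expected (Fisher p = 4.07e-06). Cap-H2, mir-4948, lncRNA:CR45791 and asRNA:CR46047 were higher and CG2818, CG9380, CG31955 and CR33255 lower. A difference between the stocks shared by both tissues would be consistent with these 8, as would an effect of the mutation in both.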
